A study of Mus musculus with 28 samples.

How the data were processed

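RNA was sequenced from pancreatic islets of 28 male mice, 1 library per mouse, in 4 labelled groups. Control mice (Klf6 flanked by loxP sites, no Cre) and βKlf6KO mice (the same floxed alleles plus Cre recombinase inserted in 1 Ins1 allele, which acts in β cells) were given saline or S961, a peptide that blocks the insulin receptor. The labels gave 6 control and 6 βKlf6KO libraries after saline and 8 of each after S961. Per the labels' protocols, islets were picked by hand, kept overnight in culture, and poly(A) RNA libraries with strand information were read as single ends. Each library was a separate mouse, so p-values refer to the spread between mice.

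The values were log2 CPM (read counts scaled to the library size) deposited by the authors in 1 table of 14219 genes by 28 libraries. Per the submitters' processing notes, the tools were STAR 2.5.3a, HTSeq 0.9.1 and edgeR, on the build GRCm38. How reads on each strand were assigned is not given in the sources used here, so overlapping and antisense genes may share reads. The deposited log2 values had the form of log2 of a read count plus 0.5 over a scaled library size. Inverting that form gave whole reads within 0.05 for 100% of values in every library, with 28868638 to 45001633 reads over the listed genes per library. At that depth a count of 0 allowed at most 3 reads, or 0.069 to 0.105 CPM, a limit that covers counting error only. Every column matched 1 library title, and none was left unmatched.

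Gene symbols were those of the table. For 820 rows with no symbol and 97 rows with a number or date in its place, the symbol came from GENCODE M21 by Ensembl ID where that gave one, as for duplicated symbols, and 14210 IDs were found there. Coordinates are from GENCODE M21 on GRCm38.

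The deposited log2 values were used without further scaling. Genes with at least 1 CPM in at least 6 libraries were kept, which left 13591 and removed 628. Group means were fitted to all 28 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The 5 contrasts were S961 against saline in each genotype, genotype within each treatment, and the difference of the S961 responses. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Every adjusted p of a single gene below is from limma unless a sentence names an exact test.

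A total of 31 gene lists, the tests and the rule for named genes were fixed before the data were examined, and 29 had the 5 measured members needed for a test. Lists were tested with camera in limma at a preset correlation of 0.01. The alternatives were camera with an estimated correlation, fry, and an exact permutation test of the list mean per mouse. Single measures were compared between groups by exact permutation tests in a family of 24, with Benjamini-Hochberg adjustment. Of these measures, Klf6 and Ins1 were in the fixed plan, while Ins2, the Ins1 to Ins2 ratio and Mki67 were not. Named genes were Klf6, Ins1 and Ins2 in every comparison. To these were added the 8 highest and 8 lowest log2 differences among called genes with a mean of at least 4 CPM in the higher group and a symbol that is not a predicted name. Each list with a call gave up to 3 called members with the smallest p, or its 1 member with the smallest p where none was called. A comparison without calls gave its 5 genes with the smallest p. In comparisons without calls the list members are left out, except where a list is described. Any other gene is said to have been chosen after its values were seen.

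The fit was tested on simulated data, in which residuals of the 28 libraries were permuted and 200 of 13591 genes were changed, in 20 simulations per comparison. For genotype after saline, 67.6% of 2-fold and 93.8% of 4-fold changes were recovered, and for genotype after S961 75.6% and 96.4%. For S961 in control islets 71.1% and 95.2% were recovered, in βKlf6KO islets 70.4% and 95.8%, and for the difference of responses 51.9% and 86.1%. The median number of unchanged genes called was 0.5 to 2 per simulation, but single simulations called up to 8133. The cause of those high numbers was not tested.

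Among 86 pairs of libraries within groups, the smallest chi-square per degree of freedom over genes was 33.4, so no pair agreed within sampling noise. The alternatives were a floor at 1 CPM, no filter, a filter at 5 CPM, robust moderation, no trend, library weights, a fit of only the groups compared, lane and replicate number as covariates, quantile and median scaling, and each library left out. Chosen after seeing the data were voom weights, a fit without 3 libraries, the first principal component or the lymphocyte and macrophage list means as covariates, no scaling factor, and a correction for transcript GC content in 20 bins.

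The targeted gene did not follow the genotype labels, and a second check of genotype did not follow them after saline, as the report gives first. Groups are therefore called labelled groups throughout, no library was moved or left out of the main results, and every direction is that of the labels.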

Results

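The series measured the transcriptome of islets after saline or after S961. The mice were labelled as lacking the transcription factor Klf6 in β cells or as controls. The labels name the question as which genes differ between control and βKlf6KO islets under each treatment. There were 6 libraries labelled control saline, 8 labelled control S961, 6 labelled βKlf6KO saline and 8 labelled βKlf6KO S961. Reads over listed genes ranged from 28868638 to 45001633 per library.

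Klf6 RNA was not lower in the libraries labelled βKlf6KO. Klf6 (ENSMUSG00000000078, GRCm38 chromosome 13, 5861482 to 5870394, plus strand) stood at 7.0 ± 0.42 log2 CPM (SD, n = 6) in libraries labelled control saline and 6.97 ± 0.26 (n = 6) in those labelled βKlf6KO saline. It stood at 6.94 ± 0.72 (n = 8) in libraries labelled control S961 and 7.22 ± 0.51 (n = 8) in those labelled βKlf6KO S961. The labelled genotype difference was -0.03 after saline (exact permutation p = 0.890, adjusted 0.890) and 0.28 after S961 (exact permutation p = 0.389, adjusted 0.584). Counts per gene do not separate the deleted exons from the rest, and islets hold other cells that keep Klf6, so this measure alone is a weak check.

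Single libraries are given because Klf6 is the targeted gene. Labelled control saline replicates 1 to 6 had 6.89, 6.92, 6.35, 7.67, 7.11 and 7.05. Labelled control S961 replicates 1 to 8 had 6.83, 7.11, 6.68, 6.75, 6.18, 6.21, 7.34 and 8.42. Labelled βKlf6KO saline replicates 1 to 6 had 6.69, 6.84, 7.13, 7.41, 6.79 and 6.95. Labelled βKlf6KO S961 replicates 1 to 8 had 7.46, 6.65, 6.38, 7.52, 7.01, 7.55, 7.22 and 7.94.

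The ratio of the insulin genes is a sharper check, because βKlf6KO mice carry Cre in 1 Ins1 allele and controls carry none. Ins1 lies on chromosome 19 (52264297 to 52265476, plus strand) and Ins2 on chromosome 7 (142678656 to 142743381, minus strand). The log2 ratio of Ins1 to Ins2 was -1.63 ± 0.77 (SD, n = 6) in libraries labelled control saline and -1.29 ± 0.27 (n = 6) in those labelled βKlf6KO saline, a difference of 0.34 (exact permutation p = 0.357, adjusted 0.584). It was -1.31 ± 0.69 (n = 8) in libraries labelled control S961 and -1.94 ± 0.48 (n = 8) in those labelled βKlf6KO S961, a difference of -0.62 (exact permutation p = 0.0558, adjusted 0.149). Labelled control saline replicates 1 to 6 had ratios of -1.34, -2.29, -2.35, -0.49, -2.23 and -1.11, and labelled βKlf6KO saline replicates 1 to 6 had -1.81, -1.26, -1.13, -1.24, -1.05 and -1.26. Labelled control S961 replicates 1 to 8 had -1.19, -0.26, -0.77, -1.01, -2.38, -1.36, -2.11 and -1.43, and labelled βKlf6KO S961 replicates 1 to 8 had -0.86, -2.19, -2.25, -1.63, -1.98, -2.12, -2.24 and -2.20. The ratio therefore did not fall with the βKlf6KO label after saline, and after S961 it was lower in libraries labelled βKlf6KO without passing the test. Directions drawn from the labels below carry that doubt. Ins1 itself differed by 0.55 after saline (exact permutation p = 0.249) and -0.31 after S961 (exact permutation p = 0.535), and Ins2 by 0.21 (exact permutation p = 0.887) and 0.31 (exact permutation p = 0.646).

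**Figure D1:**
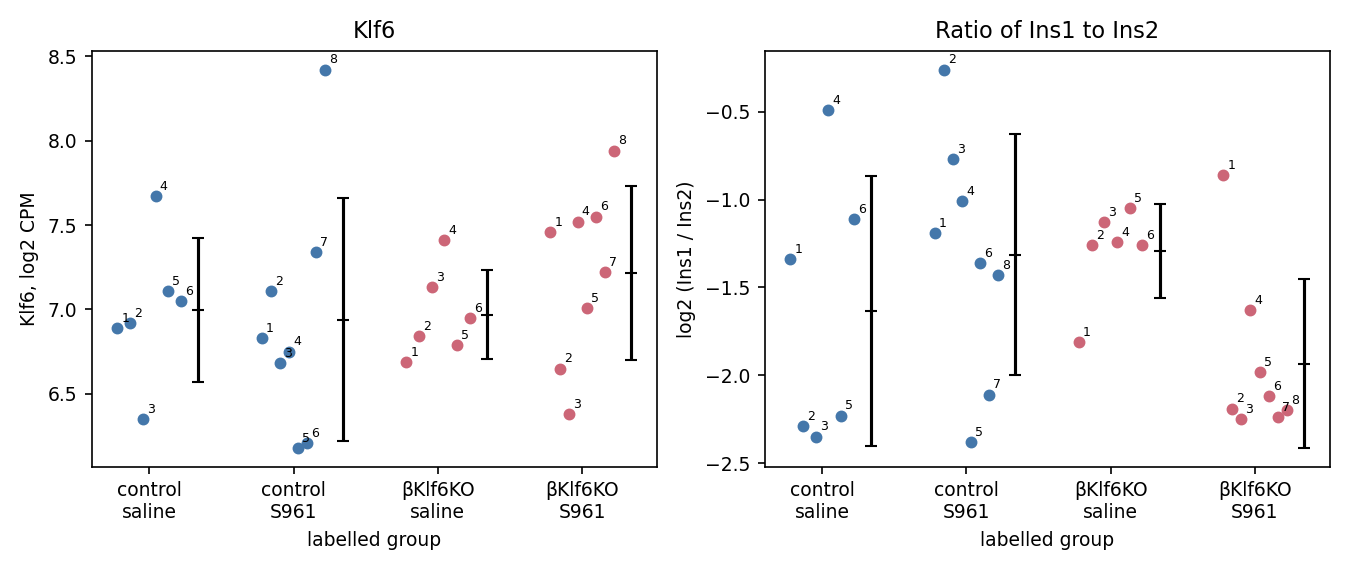
Klf6 in log2 CPM and the log2 ratio of Ins1 to Ins2 in each library, by labelled group, with the group mean and SD as bars and replicate numbers beside the points. Labelled βKlf6KO libraries do not lie below labelled controls in Klf6, and ratios near -2.2 occur in both genotypes.

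Sequencing lane was a possible batch, and every lane held libraries of all 4 labelled groups. Within lanes 4, 5, 6 and 7 the labelled genotype difference of the Ins1 to Ins2 ratio was 0, 1.15, 0.12 and -0.05 after saline and -0.15, -0.76, -1.12 and -0.45 after S961. The Klf6 difference in those lanes was -0.22, 0.63, 0.02 and -0.18 after saline and 0.70, 0.19, 0.52 and -0.30 after S961. Each lane value rests on 1 or 2 libraries per group.

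Libraries also differed along a component that ran with GC content, described after the data were seen. The first principal component held 54.9% of the variance, and across genes its loadings ran with the GC content of the longest transcript (Spearman -0.845 over 13584 genes, which are not independent replicates). The highest scores were 139.6 for labelled control S961 replicate 2, 98.4 for labelled control saline replicate 4 and 79.8 for labelled control S961 replicate 8. Ins2 in these libraries was 12.31, 13.16 and 13.57 log2 CPM. The second component held 16.6%.

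**Figure D2:**
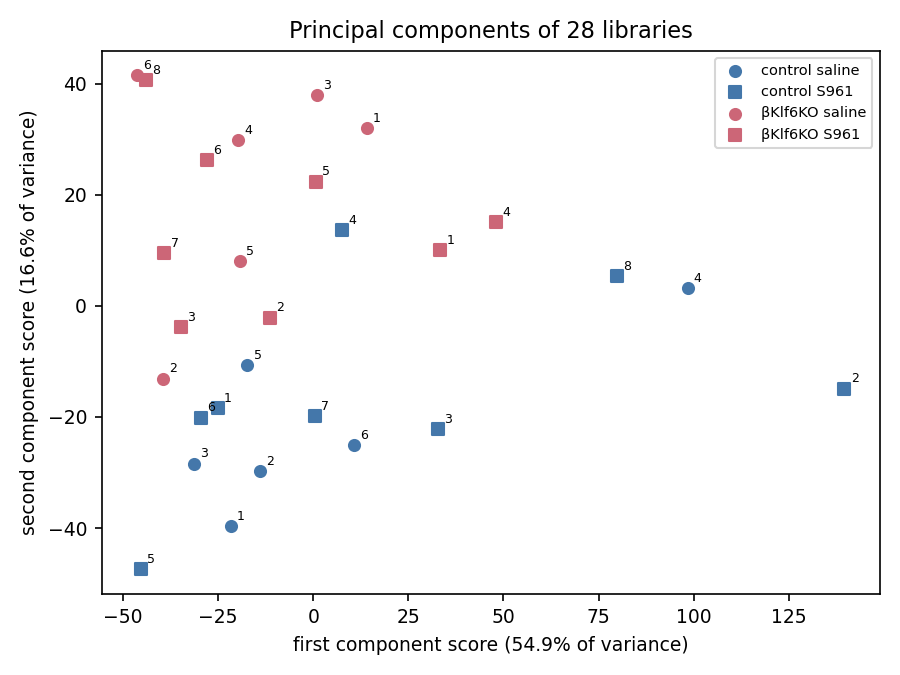
Scores of the 28 libraries on the first and the second principal component, in arbitrary units, by labelled group (colour for genotype, circles for saline, squares for S961), with replicate numbers. A total of 3 libraries labelled control lie at first component scores of 79.8 to 139.6.

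After saline, genes of cell division were higher in the libraries labelled βKlf6KO than in those labelled control. The cyclin Ccnb2 was higher by 4.02 ± 0.74 on the log2 scale (SE; adjusted p = 0.00169) and the spindle protein Hmmr by 3.99 ± 0.65 (adjusted p = 6.95e-04). Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361, minus strand), was higher by 3.50 ± 0.55 (adjusted p = 5.71e-04), from 0.77 ± 1.06 (SD, n = 6) to 4.27 ± 0.30 (n = 6) log2 CPM. All 6 libraries labelled βKlf6KO lay above the control mean for each of these genes. Because Klf6 and the Ins1 to Ins2 ratio did not follow the labels, these are differences between labelled groups.

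In all, 378 of 13591 genes passed the test, 284 higher and 94 lower in libraries labelled βKlf6KO saline, and 199 and 11 of these by at least 2-fold. Of the 49 measured genes of the proliferation list, 37 were higher and none lower over all genes tested, and 43 were higher adjusted over the list alone, with a median log2 difference of 2.26. The list rose by camera (adjusted p = 3.72e-59) and held with an adjusted p = 0.00638 with an estimated correlation and an exact adjusted p = 0.0314. The 37 calls became 13 of 25 measured members with a filter at 5 CPM and 0 with lymphocyte and macrophage means as covariates, at medians of 1.25 and 2.08. Further members were Ube2c at 3.62, Ccnb1 at 3.53, Ccna2 at 3.41, Cdc20 at 3.38, Birc5 at 3.30, Cdc6 at 2.33 and Bub1b at 1.92. Ckap2l, which is not on the list, was higher by 3.39. Within lanes 4, 5, 6 and 7 the list mean differed by 2.07, 2.34, 1.65 and 2.48.

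Some markers of immune and connective tissue cells were higher too, 5 of 23 macrophage, 2 of 8 lymphocyte and 2 of 23 fibroblast genes. None of these 3 lists passed with an estimated correlation, as given below, or in the exact test of the mean per mouse (adjusted p = 0.0628, 0.0628 and 0.0785), while fry gave an adjusted p = 0.00487, 0.0108 and 0.0465. Of the macrophage genes 5 were higher over all genes tested and 17 adjusted over the list alone, the 5 being the colony-stimulating factor receptor Csf1r at 1.12, Fcgr3 at 1.04, the class II gene H2-Aa at 1.34 and, chosen after their values were seen, Ctss at 0.77 and Lyz2 at 1.68. The list rose by camera (adjusted p = 9.11e-16), but had an adjusted p = 0.0746 with an estimated correlation. Of 8 lymphocyte genes 2 were higher over all genes and 7 adjusted over the list alone, with a median of 3.27 (camera adjusted p = 6.18e-07, adjusted p = 0.148 with an estimated correlation). The B cell gene Cd22 was higher by 2.40 ± 0.51. Of 23 fibroblast and stellate cell genes 2 were higher over all genes and 5 adjusted over the list alone, Col3a1 by 1.44 and Col1a2 by 1.5 (camera adjusted p = 5.23e-08, adjusted p = 0.235 with an estimated correlation). Of libraries labelled saline left out in turn, the macrophage count was 2, 1, 3, 3 and 2 without control replicates 1, 2, 3, 4 and 6, and 3, 12, 1, 1, 10 and 1 without βKlf6KO replicates 1 to 6. The lymphocyte count was 5 without βKlf6KO replicate 2, and 1 without control replicates 1, 2, 5 or 6 or βKlf6KO replicates 1, 3, 4 or 6. The fibroblast count was 0 without control replicates 1 or 6 or βKlf6KO replicates 3 or 6, 1 without control replicate 2 or βKlf6KO replicate 1, 7 without βKlf6KO replicate 2, and 4 without labelled control S961 replicate 2. Over the other settings the 3 counts ran from 0 to 21, 0 to 7 and 0 to 19, highest with library weights and 0 with lymphocyte and macrophage means as covariates. Those covariates are the means of the macrophage and lymphocyte lists themselves. For these lists the 0 follows from the setting and does not test them.

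Of 37 β-cell identity genes 4 passed the test after saline. Of these 1 was higher, the granule protein Chgb by 1.04, and 3 were lower, the granule protein Sytl4 by -0.75, the transcription factor Nkx6-1 by -0.48 and, chosen after its value was seen, the glucose transporter Slc2a2 by -0.73. Adjusted over the list alone, 2 were higher and 3 lower, with a median of -0.18 (camera adjusted p = 0.0191, adjusted p = 0.509 with an estimated correlation). Of the 4 calls 0 were left without labelled control saline replicate 1 or βKlf6KO saline replicate 4, 1 without control replicate 4 or βKlf6KO replicates 1 or 6, and 2 without control replicates 2, 3 or 6 or βKlf6KO replicates 3 or 5. With library weights 3 were higher and 15 lower, with the first component 2 and 10, without the 3 libraries 1 and 5, after the GC correction 2 and 4, with a filter at 5 CPM or median centring 1 and 1, and with lymphocyte and macrophage means none. Of 13 dedifferentiation and progenitor genes 1 was higher over all genes tested, Serpina7 by 2.14 ± 0.38 (adjusted p = 0.00131), and 4 adjusted over the list alone (camera adjusted p = 0.00951, adjusted p = 0.0746 with an estimated correlation), and 2 were higher without labelled βKlf6KO saline replicate 2. Over the other settings 0 to 5 were higher, and fry and the exact test gave an adjusted p = 0.00697 and 0.0314. The vitamin D binding protein gene Gc, on the α-cell list, was higher by 1.79, and the respiratory chain gene Ndufa1 by 0.97. Among called genes of at least 4 CPM with a symbol that is not a predicted name, the lowest log2 differences were those of T2 (-1.04), Ttc28 (-1.01), the mitochondrial ribosomal RNA mt-Rnr2 (-0.99), Mcoln3 (-0.96), Mxra7 (-0.96), Thsd4 (-0.96), Aldh5a1 (-0.84) and Mlph (-0.83).

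Single called members of other lists after saline were Oat at 0.54, the cell cycle inhibitor Cdkn2c at 0.60, the complement gene C3 at 1.65, the oxygen sensor Egln3 at 1.12, Foxo3 at -0.26 and Vamp2 at -0.41. Members with the smallest p in lists without a call were Fdft1 at 0.21, Slc16a3 at 1.26, Fos at 1.06, Gbp3 at 0.83, Gpt2 at 0.47 and the mitochondrially encoded ND2 at -0.85, none of which passed the test.

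Of the 38 named calls after saline 21 held when any 1 library was left out, and the highest adjusted p without 1 library was 0.141, for Oat without labelled βKlf6KO saline replicate 6. When only the 2 groups compared were fitted 30 of the 38 were called. With lymphocyte and macrophage means 2 were, and the calls of Ccnb2, Hmmr and Mki67 ended at differences of 3.45, 4.07 and 3.38. The number of calls depended on single libraries. It was 214 without labelled control replicate 1, 230 without 2, 243 without 3 and 234 without 6, and 242, 217 and 214 without labelled βKlf6KO replicates 3, 4 and 6. It was 117 with a filter at 5 CPM, 3018 with library weights, 690 without the 3 libraries of highest first component score, 1370 after a GC correction, 2821 with the first component as a covariate and 8 with lymphocyte and macrophage means as covariates, the last 4 chosen after seeing the data. Without the deposited scaling factor, also chosen then, 265 genes were higher and 46 lower, and after the GC correction 785 and 585. With library weights 1564 were higher and 1454 lower, and with the first component the balance turned, to 1227 and 1594.

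**Figure D3:**
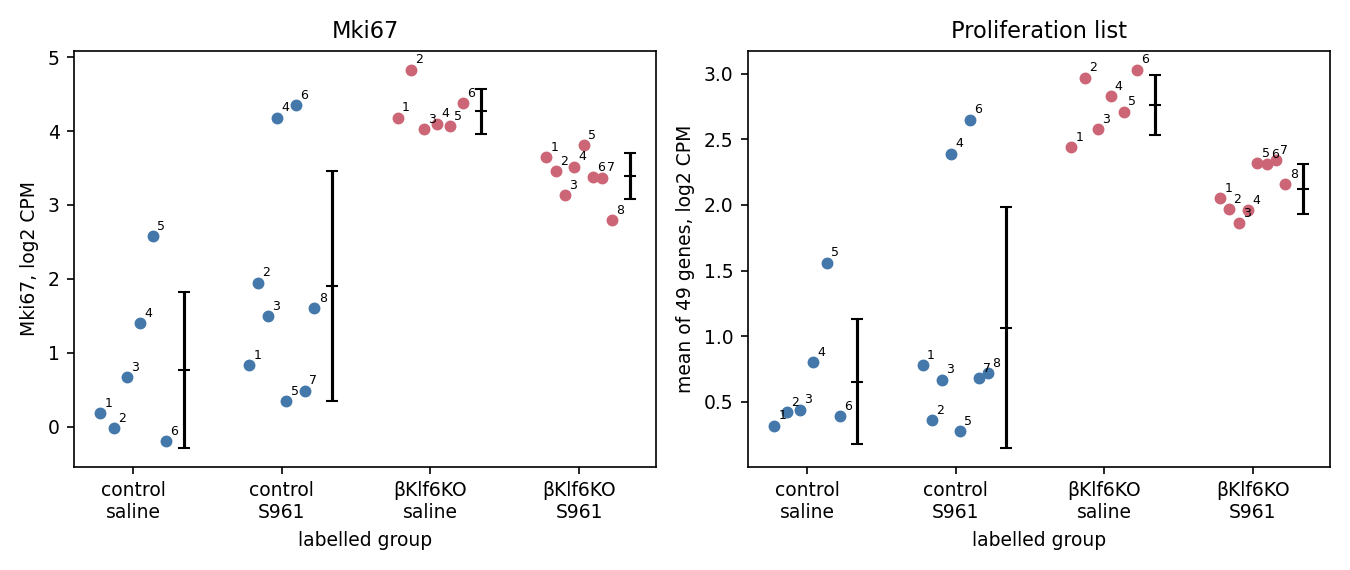
Mki67 and the mean of the 49 measured proliferation genes in log2 CPM in each library, by labelled group, with the mean and SD as bars and replicate numbers. All 14 libraries labelled βKlf6KO have a list mean of at least 1.86, and labelled control S961 replicates 4 and 6 reach 2.39 and 2.65.

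After S961, 8 of 37 β-cell genes were lower, and 13 of 49 proliferation and 10 of 23 fibroblast and stellate cell genes higher, in the libraries labelled βKlf6KO than in those labelled control. Each of these 3 lists had an adjusted p = 0.131 with an estimated correlation, while fry gave 0.00421, 0.00394 and 0.00242 and the exact test of the mean per mouse 0.0950, 0.0335 and 0.00751. The glucose transporter Slc2a2 was lower by -0.88 ± 0.17 on the log2 scale (SE; adjusted p = 0.00611), Sytl4 by -0.90 ± 0.16 (adjusted p = 0.00511) and the β-cell transcription factor Pdx1 (chromosome 5, 147269959 to 147275848, plus strand) by -0.47 ± 0.08 (adjusted p = 0.00450). The secreted protein gene Spp1 was higher by 1.16 ± 0.21 (adjusted p = 0.00502) and the smooth muscle actin Acta2 by 1.80 ± 0.39 (adjusted p = 0.0145). All 8 libraries labelled βKlf6KO lay beyond the labelled control mean for each of these genes. The doubt about the genotype labels holds here too for Klf6, while the Ins1 to Ins2 ratio was lower in libraries labelled βKlf6KO without passing the test.

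In all, 593 of 13591 genes passed the test, 320 higher and 273 lower in libraries labelled βKlf6KO S961, with 124 and 7 by at least 2-fold. Of 37 β-cell identity genes 8 were lower and 1 higher (Chgb, chosen after its value was seen) over all genes tested, and 15 and 1 adjusted over the list alone, with a median of -0.32. Camera gave an adjusted p = 3.69e-07, and an adjusted p = 0.131 with an estimated correlation. Lower calls were 4 without labelled control S961 replicates 3 or 5 or βKlf6KO S961 replicate 8, 3 without βKlf6KO replicate 6, and 1 when only the 2 groups compared were fitted or with lymphocyte and macrophage means. They were 12 after the GC correction and 22 with the first component. Of 13 dedifferentiation and progenitor genes 4 were higher over all genes and 6 adjusted over the list alone, and the list rose (camera adjusted p = 8.69e-05, adjusted p = 0.0140 with an estimated correlation). They included Serpina7 by 1.69 ± 0.33, the aldehyde dehydrogenase Aldh1a3 by 1.02 ± 0.25, the gastrin gene Gast by 1.78 ± 0.50, near 1 CPM, and, chosen after its value was seen, Vim by 0.93. The 4 calls became 1 without labelled control S961 replicates 2 or 3, and 2 without control S961 replicate 5, control saline replicates 2, 3 or 6, βKlf6KO saline replicates 3, 4 or 5, or βKlf6KO S961 replicates 3, 5, 6, 7 or 8. They became 0 when only the 2 groups compared were fitted, 1 after quantile normalization or with lymphocyte and macrophage means, 2 with a floor at 1 CPM, 7 after the GC correction and 9 with the first component.

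Of 49 proliferation genes 13 were higher over all genes tested and 37 adjusted over the list alone, with a median of 1.06 (camera adjusted p = 4.27e-17, adjusted p = 0.131 with an estimated correlation). Ccnb1 was higher by 1.88, Ccna2 by 1.80, Birc5 by 1.75, Cdk1 by 1.51 and Ccne1 by 0.49. The 13 calls became 2, 1, 32, 3 and 32 without labelled control S961 replicates 2, 3, 4, 5 and 6, and 5, 2, 2 and 2 without labelled βKlf6KO S961 replicates 5, 6, 7 and 8. They became 0 when only the 2 groups compared were fitted or with lymphocyte and macrophage means, at medians of 1.06 and 0.91, 2 after quantile normalization, 5 of 25 with a filter at 5 CPM, 6 without the 3 libraries, 7 with a floor at 1 CPM or library weights, 22 with voom weights, 34 with the first component and 35 after the GC correction. Within lanes 4, 5, 6 and 7 the list mean differed by 0.42, 1.82, 0.42 and 1.55. Of the cell cycle inhibitor list, Cdkn1a was higher by 0.76, and the cyclins Ccnd1 and Ccnd2 were lower by -0.28 and -0.34.

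Of 23 fibroblast and stellate cell genes 10 were higher over all genes tested and 17 adjusted over the list alone, including the collagens Col1a2 by 1.57 and Col3a1 by 1.40 (camera adjusted p = 1.59e-12, adjusted p = 0.131 with an estimated correlation). Its count was 6 without labelled control S961 replicate 5 or βKlf6KO S961 replicates 5 or 6, 4 when only the 2 groups compared were fitted, and 0 with lymphocyte and macrophage means. Of 30 acinar genes 3 were higher over all genes, Prss3 by 2.11, Try5 by 1.45 and Spink1 by 1.30, and adjusted over the list alone 16 were higher and 1 lower (camera adjusted p = 8.20e-10, adjusted p = 0.277 with an estimated correlation). Trypsin genes are near-identical, so reads of Prss3 and Try5 may be shared. The acinar calls became 6, 1, 1, 7 and 11 without labelled control S961 replicates 1, 2, 3, 7 and 8, 1 of the 11 lower. Over the other settings 0 to 10 acinar genes were higher and at most 1 lower, lowest when only the 2 groups compared were fitted or with lymphocyte and macrophage means and highest after the GC correction. Of 16 ductal genes 1 was higher over all genes, Spp1, and 7 adjusted over the list alone (camera adjusted p = 6.47e-05, adjusted p = 0.150 with an estimated correlation). The ductal count was 3 without labelled control S961 replicates 7 or 8, and 2 without control saline replicate 4 or βKlf6KO S961 replicates 1 or 2. Of 23 macrophage genes 1 was higher, Cd14 by 1.09, and 1 adjusted over the list alone (camera adjusted p = 7.41e-06, adjusted p = 0.277 with an estimated correlation). The macrophage count was 2 without labelled control S961 replicate 1, and 0 without control S961 replicates 2, 3 or 5 or βKlf6KO S961 replicates 6, 7 or 8. Over the other settings it was 0 to 5. The exact adjusted p was 0.0586 for acinar, 0.0351 for ductal and 0.0351 for macrophage genes, and fry gave 0.0329, 0.00710 and 0.0329. No lymphocyte gene passed over all genes tested, and 1 of 8 was higher adjusted over the list alone (median 0.94, camera adjusted p = 0.107).

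Of 35 genes of the unfolded protein response 4 were lower over all genes tested and 8 adjusted over the list alone, namely the chaperone Calr by -0.40, Pdia4 by -0.38, Atf6 by -0.40 and, chosen after its value was seen, Pdia6 by -0.34 (camera adjusted p = 0.00232, adjusted p = 0.131 with an estimated correlation). The 4 calls became 2 without labelled control S961 replicates 2, 3 or 5 or βKlf6KO S961 replicates 6, 7 or 8, 0 when only the 2 groups compared were fitted or with lymphocyte and macrophage means, 1 after quantile normalization, 11 after the GC correction and 15 with the first component. Of 27 genes normally silent in β cells 2 were higher, Igf1 by 0.90 and Tpm2 by 1.16, and 8 adjusted over the list alone (camera adjusted p = 9.86e-09, adjusted p = 0.150 with an estimated correlation). Hypoxia genes Ddit4 and Bhlhe40 were higher by 0.69 and 0.52, 2 of 15 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.131 with an estimated correlation). The exact adjusted p of these 3 lists was 0.118, 0.0335 and 0.00751, and fry gave 0.00394, 0.00517 and 3.01e-04. In fits that left out 1 library the 2 calls of each of these last 2 lists ran from 0 to 4 and from 0 to 3, moving by over 1.5 times in 19 and 22 of 28. Both were 0 without labelled control S961 replicates 2, 3 or 5 or βKlf6KO S961 replicates 6, 7 or 8, and the first also without control S961 replicate 4 or βKlf6KO S961 replicate 5. Islets hold other cells, and 10 of 23 fibroblast and stellate cell genes were higher after S961 too. Calls among genes normally silent in β cells, or among dedifferentiation genes, therefore cannot be placed in β cells.

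Other called members after S961 were Gc at 1.20, Slc7a2 at -0.58, Etv4 at 1.57, Ndufa1 at 0.68, the receptor Igf1r at -0.43, Matn2 at -0.52, the prolactin receptor Prlr at -0.90, Klf11 at 0.28, Gpt2 at 0.44, Vamp2 at -0.44 and Hspb8 at 0.60. Among called genes of at least 4 CPM with a symbol that is not a predicted name, the highest log2 differences besides those above were Reg3a (2.37), the complement gene C4b (2.20), Itih4 (2.14) and C1qtnf1 (2.13), and the lowest Mcoln3 (-1.05), Ttc28 (-0.94), Hpgds (-0.93), the galanin receptor Galr1 (-0.91) and Aldh5a1 (-0.90). Members with the smallest p in lists without a call were Ier3 at 0.82, Cxcl16 at 0.72, Erbb3 at 0.65 and ND5 at -0.59, which did not pass the test.

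Of the 49 named calls after S961 24 held when any 1 library was left out, and the highest adjusted p was 0.111, for Bhlhe40 and Prlr without labelled βKlf6KO S961 replicate 8. When only the 2 groups compared were fitted 8 of the 49 were called, and with lymphocyte and macrophage means 4 were. The calls of Slc2a2 and Sytl4 ended in both, at differences of -0.88 and -0.90 in the first and -0.59 and -0.66 in the second, and that of Acta2 in the second at 1.06, while Pdx1 and Spp1 were called in both. The number of calls was 216, 189 and 244 without labelled control replicates 2, 3 and 5, and 346, 177, 211 and 192 without labelled βKlf6KO replicates 5, 6, 7 and 8. It was 35 when only the 2 groups compared were fitted, 395 after quantile normalization, and 858 without the 3 libraries of highest first component score. It was 2549 after a GC correction, 3829 with the first component as a covariate and 14 with lymphocyte and macrophage means as covariates, and these 3 and the fit without 3 libraries were chosen after seeing the data. Without the deposited scaling factor, also chosen then, 275 genes were higher and 130 lower. The balance turned to more lower calls with a filter at 5 CPM (218 higher, 265 lower), library weights (260 and 300), median centring (233 and 238), quantile normalization (176 and 219), the GC correction (1190 and 1359), the first component (1639 and 2190) and lymphocyte and macrophage means (6 and 8).

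**Figure D4:**
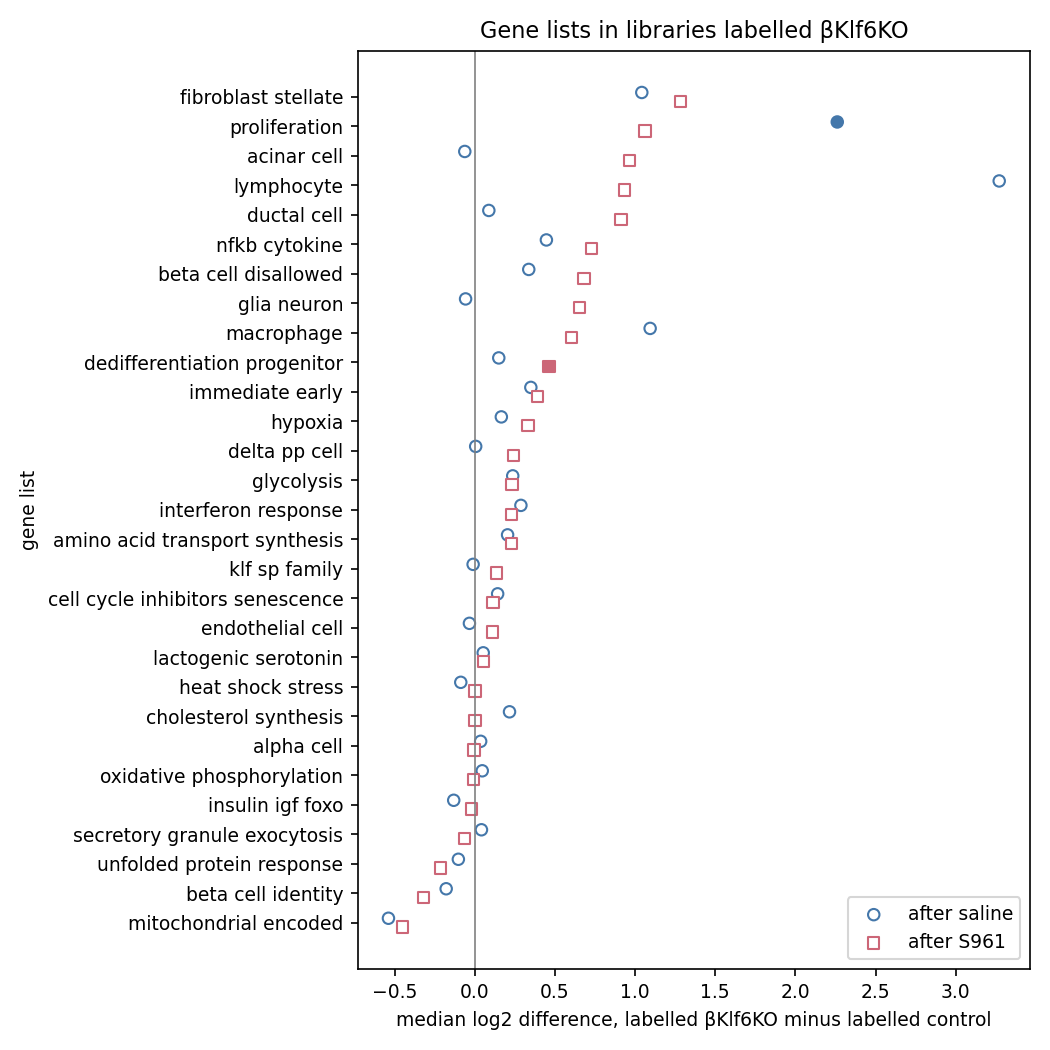
Median log2 difference of each tested gene list, labelled βKlf6KO minus labelled control, after saline (circles) and after S961 (squares). Filled symbols have a camera adjusted p under 0.05 with an estimated correlation, which holds for proliferation after saline (2.26) and for dedifferentiation after S961 (0.46).

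The genotype comparisons under the 2 treatments share no libraries. Their log2 differences correlated across genes with r = 0.68, against a mean of 0.043 and a range of -0.789 to 0.865 in 100 simulations of unchanged groups, so the correlation lay within that range. The covariance was 0.123, against a simulated mean of 0.0062. A total of 68 genes were called higher in both, where independent lists of 284 and 320 genes would share 6.7, and 60 were called lower in both, where 94 and 273 would share 1.9. No gene was called in opposite directions. Genes are correlated and shared calls were not simulated, so the 6.7 and 1.9 do not test the overlap.

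No gene of 13591 passed the limma test between S961 and saline in the libraries labelled control. An unadjusted p under 0.05 was found for 104 genes, where chance gives 680 on average. In 100 splits of these libraries, the real 1 among them, the median of the others was 253, and 29 had fewer than 104. The 5 genes with the smallest p were Synpo2 (0.66), Ube4b (0.51), the uncharacterized 2610035D17Rik (-0.67), Ptpro (-1.02) and Mir670hg (0.48), all with an adjusted p = 0.973. Klf6 differed by -0.06 (adjusted p = 0.974), Ins1 by -0.12 and Ins2 by -0.44. The proliferation list had a median of 0.42 and no member called by limma (camera adjusted p = 1.34e-11, adjusted p = 0.523 with an estimated correlation). Of the other cell type lists, acinar genes had a median of -0.62 (adjusted p = 0.328 with an estimated correlation). For the proliferation and acinar lists fry gave an adjusted p = 0.998, and the exact test of the mean per mouse 0.995.

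In the libraries labelled βKlf6KO no gene passed the limma test between S961 and saline, and 413 had an unadjusted p under 0.05. In 100 splits of these libraries, the real 1 among them, the median of the others was 128. Of these splits 85 had fewer than 413, which was thus toward the high end. The mean of the proliferation list was lower after S961, 2.12 ± 0.19 (SD, n = 8) against 2.76 ± 0.23 (n = 6) log2 CPM. Every library labelled S961 lay below every library labelled saline (exact permutation p = 3.33e-04, the smallest the design allows). Adjusted, this was 0.00966 among the lists and 0.00400 among the single measures. Camera gave an adjusted p = 7.72e-26 and an adjusted p = 0.127 with an estimated correlation, and limma called no single member. Of 8 lymphocyte genes none was lower over all genes tested and 3 were lower adjusted over the list alone, with a median of -1.93 (camera adjusted p = 1.62e-11, adjusted p = 0.127 with an estimated correlation). Fry gave an adjusted p = 0.400 for the proliferation and lymphocyte lists, and the exact test of the mean per mouse 0.547 for lymphocyte genes. Mki67, not named by the rule in this comparison and outside the fixed plan of exact tests, was lower by -0.88 (exact permutation p = 3.33e-04, the smallest the design allows, adjusted 0.00400). Ins1 differed by -0.98 (exact permutation p = 0.0110, adjusted 0.0440; limma adjusted p = 0.9997), and Ins2 by -0.34. The 5 genes with the smallest p were S100a13 (-0.44), Slc16a9 (-0.37), Nt5e (-1.53), Grem1 (-3.16) and Gm10557 (0.39), none of which passed. With values under 1 CPM set to that floor 11 genes were called, and 2 with library weights.

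No gene passed the limma test for a difference of the S961 response between labelled genotypes, and 350 had an unadjusted p under 0.05. In 100 splits, the real 1 among them, the median of the others was 190, and 64 had fewer than 350. The smallest p belonged to Synpo2 (-0.97), Rad54l (-1.77), Ube4b (-0.77), Mir670hg (-0.84) and Exo1 (-2.13). The proliferation list had a median difference of -1.20 (camera adjusted p = 4.60e-36, adjusted p = 0.0718 with an estimated correlation), and the acinar list 1.10 (camera adjusted p = 1.43e-24, adjusted p = 0.0906 with an estimated correlation). The lymphocyte, macrophage and ductal lists had medians of -2.50, -0.41 and 0.75. For these camera gave an adjusted p = 1.93e-06, 1.82e-06 and 3.14e-07, and 0.166, 0.257 and 0.0906 with an estimated correlation. Fry gave an adjusted p = 0.390 for the proliferation, acinar and ductal lists, 0.487 for the lymphocyte list and 0.525 for the macrophage list.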

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

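The tests of explanations, apart from the splits of libraries, were chosen after the results were seen. Each of 100 measures was tested in 4 groups for a library far from the rest of its group by Dixon's test, and 30 of 400 tests were past the 95% limit where chance gives 20.

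Labelled control saline replicate 4, one of the libraries with a high first component score, accounted for 7 of them. Its gap over the group's range was 0.733 for Ins2, 0.696 for 2610035D17Rik, 0.682 for Chgb, 0.83 for Ndufa1, 0.644 for ND2, 0.649 for Prlr and 0.638 for ND5. Labelled control saline replicate 5 stood apart in C4b (0.677), Ccnd2 (0.626) and Ddit4 (0.701), replicate 3 in Egln3 (0.723) and replicate 1 in Col1a2 (0.631). In labelled control S961, replicate 2 stood apart in Galr1 (0.559) and Hspb8 (0.531), replicate 3 in Nt5e (0.695), replicate 4 in C3 (0.606), replicate 5 in Reg3a (0.634) and replicate 8 in Igf1 (0.546). In labelled βKlf6KO saline, replicate 2 stood apart in Ube4b (0.63), Foxo3 (0.786) and Igf1r (0.712), replicate 6 in Gc (0.706) and replicate 1 in the Ins1 to Ins2 ratio (0.727). In labelled βKlf6KO S961, replicate 8 stood apart in 2610035D17Rik (0.527), Thsd4 (0.568), H2-Aa (0.569) and Cd22 (0.559), replicate 4 in S100a13 (0.607), replicate 6 in Egln3 (0.567) and replicate 1 in the Ins1 to Ins2 ratio (0.555).

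The ratio of Ins1 to Ins2 did not fall with the βKlf6KO label after saline, while after S961 it was lower in libraries labelled βKlf6KO by -0.62 (exact permutation p = 0.0558, adjusted 0.149) and in each of 4 lanes, the direction that correct labels give. GC content bias argues poorly for the saline value, since with the first component as a covariate that difference was 0.54 ± 0.26 (SE), further from the fall that 1 missing Ins1 copy would give, and the S961 difference was -0.37 ± 0.23. Mislabelled columns remain a candidate explanation after saline, where the difference was 0.34 and ratios near -2.2 occur in libraries labelled control. The S961 difference goes with the labels, but some single libraries do not. Labelled control S961 replicates 5 and 7 had -2.38 and -2.11, the others -1.43 to -0.26. Labelled βKlf6KO S961 replicate 1, with a first component score of 33.4, had -0.86, the others -2.25 to -1.63. The libraries of highest score, labelled control S961 replicate 2 and control saline replicate 4, had the highest ratios of all, -0.26 and -0.49. Labelled control S961 replicate 8, next in score, had -1.43. Whether the ratio of single libraries runs with that score was not tested. Klf6 was not lower with the βKlf6KO label after S961 either (0.28), so mislabelling stays open there too. Which labels would be wrong was not tested, and no library was moved. The proliferation list mean was at least 1.86 in all 14 libraries labelled βKlf6KO and in labelled control S961 replicates 4 and 6. It was at most 1.56 in the other libraries labelled control. That split has the sizes of the treatments, 16 libraries labelled S961 and 12 labelled saline. Among libraries with the higher mean the ratio was -1.81 to -1.01 outside labelled βKlf6KO S961 and -2.25 to -0.86 within it. These ranges overlap, so the values do not settle 1 relabelling. The genotype itself, as a biological effect on Ins1 or Ins2 transcription, stays open as untested.

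Limma called no gene between S961 and saline, with 104 genes in labelled control and 413 in labelled βKlf6KO islets at an unadjusted p under 0.05. In the latter Mki67 and Ins1 passed exact tests (adjusted p = 0.00400 and 0.0440), that of Mki67 outside the fixed plan. There limma called 11 genes with a floor at 1 CPM and 2 with library weights. Too few libraries stays open for smaller changes, since 95.2% of simulated 4-fold but 71.1% of 2-fold changes in control islets were recovered at this size, and the list medians of proliferation genes differed by 0.42 and -0.67. For GC bias in a few libraries, the fit without the 3 libraries of highest first component score cannot decide. All 3 are labelled control, and the count in control islets was 0 with and without them. Under that fit, the GC correction and the first component, genes at an unadjusted p under 0.05 became 788, 927 and 1505 in labelled βKlf6KO islets. In control islets they became 158, 200 and 337. GC bias therefore stays open. Mislabelled libraries may account for the lack of calls, since 2 libraries labelled control, S961 replicates 4 and 6, had a high proliferation list mean. It lay above the lowest library labelled βKlf6KO, but mice that respond differently to S961 would give the same in these 2 libraries. All 6 libraries labelled βKlf6KO saline had means of 2.44 to 3.03, above the 1.86 to 2.34 of those labelled βKlf6KO S961. Differing responses to S961 would not give high means in mice that received saline. A weak response to S961 stays open as untested.

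Of 49 proliferation genes 37 after saline and 13 after S961 were higher in libraries labelled βKlf6KO, and after S961 the list had an adjusted p = 0.131 with an estimated correlation. GC bias argues poorly as the whole cause, since the median log2 difference after saline stayed at 2.21 with the first component as a covariate, against 2.26 without. Dividing lymphocytes or macrophages stay open: the macrophage gene Lyz2 stood at 5.39 and 7.07 log2 CPM in control and βKlf6KO labelled saline groups, but with their list means as covariates the median was still 2.08, and the loss of all calls there does not speak for them. For Mki67 the difference went from 3.50 ± 0.55 to 3.38 ± 0.73, so the call ended (adjusted p = 0.0573) with a wider error. Both list means differed between labelled control and βKlf6KO saline, at -1.64 and 1.36 for lymphocyte and 2.25 and 3.42 for macrophage genes. Covariates that differ between the groups by themselves widen the error of a group difference. How much of the widening came from this was not tested. An effect of genotype and mislabelled treatment or genotype both stay open.

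By splits of the libraries chance could be excluded for the number of genes called between labelled genotypes, but by simulated data it could not, nor after S961 by the splits at an unadjusted p. Of 100 splits of the libraries, only the real 1 gave 378 genes after saline, and the highest other gave 29. After S961 only the real 1 of 100 gave 593, and the highest other gave 66. In 20 simulations each, 1 called at least 378 unchanged genes after saline (4486) and 3 at least 593 after S961 (up to 8133). By genes with an unadjusted p under 0.05, 97 of the 99 other splits had fewer than the real 1953 after saline, and 89 fewer than the real 3107 after S961. For S961 in labelled control islets, in labelled βKlf6KO islets and for the difference of responses the real count was 0. Any split reaches that, so these counts cannot decide on chance. The highest other counts were 8286, 0 and 5748. Splits that call so many genes point to a structure of the samples, whose cause was not tested. Other splits with fewer genes at an unadjusted p under 0.05 than the real 104, 413 and 350 numbered 29, 85 and 64.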

How the results depend on the processing

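The fits without 3 libraries, with voom weights, without the scaling factor, with a GC correction, and with the first component or cell type means as covariates were chosen after seeing the data, and a covariate taken from the same values can inflate or remove calls. The counts of 0 for S961 in labelled control islets and for the difference of responses held under every setting run. In labelled βKlf6KO islets S961 gave 11 genes with a floor at 1 CPM and 2 with library weights. Genotype after saline (378) gave 117 with a filter at 5 CPM, 3018 with library weights, 690 without 3 libraries, 2821 with the first component, 8 with cell type means, 1370 after the GC correction, and 214 to 532 leaving out 1 library. Genotype after S961 (593) gave 35 from only the 2 groups compared, 395 after quantile normalization, 3829 with the first component, 14 with cell type means, 2549 after the GC correction, and 177 to 817 leaving out 1 library. The cause of these moves was not tested. The planned fits of recovered reads with edgeR and DESeq2 were not run.

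With the replicate number as a block, the counts were 354 after saline and 614 after S961, and 0 elsewhere. The mice are separate animals and the numbers did not pair them: the correlation of deviations had a median of -0.07 over 38 same-numbered pairs, and 2 of 28 libraries correlated best with their own number.

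Klf6, Ins1 and Ins2 differences near 0 changed sign. Klf6 after saline was 0.214 with library weights, 0.087 after quantile normalization, 0.103 without 3 libraries, 0.10 with the first component, 0.009 without the scaling factor, 0.098 after the GC correction, and -0.161 to 0.103 leaving out 1 library. Ins1 after saline was -0.043 with cell type means, and Ins2 was -0.324 with library weights, -0.317 without 3 libraries, -0.365 with the first component, -0.652 with cell type means, and -0.317 to 0.385 leaving out 1 library. After S961, Ins1 was 0.043 after quantile normalization and -0.803, past the threshold, with the first component. Ins2 was -0.015 with library weights, -0.49 without 3 libraries, -0.437 with the first component, -0.426 with cell type means, and -0.123 to 0.581 leaving out 1 library. For S961 in labelled control islets, Klf6 was 0.007 with cell type means and -0.272 to 0.073 leaving out 1 library. Ins1 there was 0.056 with library weights, 0.003 with the replicate block, 0.227 without 3 libraries, 0.145 with the first component, and -0.416 to 0.161 leaving out 1 library. Klf6 for S961 in labelled βKlf6KO islets was -0.022 with library weights. The Ins2 difference of responses was -0.172 without 3 libraries, -0.073 with the first component, and -0.33 to 0.627 leaving out 1 library.

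Among lists, proliferation for S961 in labelled βKlf6KO islets had an adjusted p = 0.127 with an estimated correlation and 0.400 with fry. After S961, β-cell identity had 0.131 with an estimated correlation and an exact adjusted p = 0.0950, and proliferation 0.131 with an estimated correlation and an exact adjusted p = 0.0335. After saline with cell type means the direction turned for β-cell identity (adjusted p = 0.714), disallowed genes (0.358), glycolysis (0.128), cytokine genes (0.714), interferon genes (0.528) and mitochondrial genes (0.781), and with the first component for glycolysis (0.739). The fibroblast list turned for the difference of responses without 3 libraries (0.742).

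Of the named genes called, 21 of 38 after saline and 24 of 49 after S961 kept their call in each of 28 fits that left out 1 library, and none changed sign. After saline the call of T2, mt-Rnr2 and Oat held in 12, 13 and 10 of those fits, and after S961 that of Bhlhe40, Prlr, Ccnd2, Gpt2, Tpm2, Gast and C4b in 5, 6, 8, 10, 10, 11 and 15. At this depth a count of 0 allows up to 0.069 to 0.105 CPM, which limits genes near that level.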

Other observations

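The component scores were described after the data were seen. Lists outside those described above gave few calls. After saline, genes of cholesterol synthesis had a median log2 difference of 0.22 in libraries labelled βKlf6KO (camera adjusted p = 0.00405, adjusted p = 0.235 with an estimated correlation), and immediate early genes 0.35 with 3 of 14 members higher adjusted over the list alone (adjusted p = 0.300 with an estimated correlation). After S961, 4 of 20 cytokine genes were higher adjusted over the list alone (adjusted p = 0.277 with an estimated correlation), and neuronal and glial genes had a median of 0.66 (adjusted p = 0.131 with an estimated correlation). Endothelial genes had medians of -0.03 after saline and 0.11 after S961, and heat shock genes -0.09 and 0.00. The 7 measured mitochondrially encoded genes had medians of -0.54 after saline and -0.45 after S961. Camera gave an adjusted p = 0.0109 and 0.0177, and 0.498 and 0.442 with an estimated correlation. The exact test of the mean per mouse gave an adjusted p = 0.0628 and 0.240.

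The second component score was above 0 in most libraries labelled βKlf6KO, with 41.5 for saline replicate 6 and 40.6 for S961 replicate 8, and -47.4 for labelled control S961 replicate 5. Across genes its loadings correlated with GC content at -0.265 and with transcript length at -0.243.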
